A study of Mus musculus with 10 samples.

How the data were processed

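Neural stem and progenitor cells (NSPCs) from mouse brain, WT or Mina53-KO, were measured by RNA-seq (3 WT and 3 KO libraries) and by CUT&Tag (2 WT and 2 KO libraries). Per the labels, the RNA-seq libraries were made from poly(A) RNA with a stranded kit, and CUT&Tag with a commercial kit. Groups and replicate numbers were taken from the sample titles and genotype labels. The submitters' processing notes name HISAT2, StringTie and the GRCm39 build, without versions. The counting tool, its strand setting, the annotation release, the peak caller and its threshold are not given in the sources used here.

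The RNA-seq table holds expected counts per Ensembl gene as deposited, not scaled, for 57180 genes, of which 525 have no symbol; part of the values are not whole, and they were rounded to whole numbers for the tests. Gene symbols, lengths and GO terms came from the same table. The authors' counts per region for CUT&Tag are whole numbers for 69418 regions merged over the 4 libraries, with a mark for each library in which the authors called a peak. The deposited RPM equal the count plus 1 divided by a library total, per the file headers and the values, which gave totals of 55710306 (WT 1), 47732697 (WT 2), 66934404 (KO 1) and 55309735 reads (KO 2). The authors' deposited log2 fold change is the log2 ratio of summed RPM, KO over WT. The deposited p-value and q-value per region are the authors', from a test not named in the sources used here. Region annotation, assigned gene and distance to the TSS are the authors' too. Coordinates are on GRCm39.

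Both assays were tested with edgeR 4.0.16 (glmQLFit with robust dispersion, glmQLFTest, TMM scaling, filterByExpr with its minimum count of 10) in R 4.3.3, KO against WT, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter kept 15298 genes, with 99.9% of the counts, and 69209 regions. The SE of a log2 fold change is its size divided by the square root of F. CPM are TMM-scaled, for CUT&Tag relative to the reads in regions. Since no spike-in or input was used here, a gain or loss of the CUT&Tag signal common to all regions cannot be measured. Leaving out a CUT&Tag library leaves 1 library in a group, which is assumed to vary like the other group.

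The comparisons, tests, alternatives, gene lists and naming rule were fixed before the data were examined. The rule named Riox2, the 10 genes with the largest positive and the 10 with the largest negative log2 fold change and the 5 with the smallest p in each direction, among called genes with a mean log2 CPM of at least 1 and non-overlapping groups, leaving out predicted and clone-named genes. It also named up to 4 members with the smallest p in each list, the 5 CUT&Tag regions with the smallest p in each direction and the region at Riox2. The further Nes regions, the chromosome 8 segment, the 3 genes called in both assays and the brain-region genes of the closing section that are not named by the rule were chosen after their values were seen. Some members of the brain-region lists are not reported here one by one.

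The 37 lists covered cell types (neural stem and radial glia, intermediate progenitor and neuroblast, neuron, astrocyte, oligodendrocyte lineage, ependymal, microglia, endothelial and pericyte, fibroblast and meningeal, erythroid), the cell cycle (S phase, G2 and M phase, cyclin-dependent kinase inhibitors and G1 regulators), p53 targets, DNA repair, apoptosis, Notch, Wnt, hedgehog, FGF and EGF, TGF-beta and BMP, arginine methylation, lysine methylation, histones, ribosome biogenesis, ribosomal proteins, interferon, MHC class I, unfolded protein response, heat shock, immediate early genes, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, extracellular matrix, sex-linked genes and neighbours of Riox2. Neighbours were listed from prior knowledge of the locus. The 32 lists with at least 5 tested members were tested with camera (limma 3.58.1; log2 CPM with a prior count of 2, inter-gene correlation 0.01), and again with an estimated correlation and with fry. Of 741 listed symbols, 3 were not found in the table. CUT&Tag reads were summed over the regions assigned to each gene and tested with camera for the genes called in RNA-seq. Overlaps of calls were tested with a two-sided Fisher's exact test over 11362 genes tested in both assays.

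Alternatives were RLE size factors, library totals, DESeq2 1.42.0, no count filter, a filter of 1 CPM in at least 3 RNA-seq or 2 CUT&Tag libraries, the replicate number as a block, no robust dispersion, glmTreat against 1.2-fold, prior counts of 0.5 and 5, and each library left out in turn. Chosen after seeing the data were the library split as a covariate, leaving out mitochondrial genes, windows of 1, 2 and 5 kb around the TSS, and the overlap of calls by reads summed per gene, with its alternatives. The planned window alternatives were meant for files with coordinates alone, so the authors' gene assignment stayed the main setting. An adjusted p that DESeq2 did not give was left out.

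RNA-seq total counts were 23562986 (WT 1), 25184724 (WT 2), 25939376 (WT 3), 19923010 (KO 1), 23899258 (KO 2) and 25639204 (KO 3). CUT&Tag reads in regions were 3125267 (WT 1), 2913959 (WT 2), 4038765 (KO 1) and 3369232 (KO 2), which is 5.61% to 6.10% of the totals. No pair of libraries lay at sampling noise: chi-square per degree of freedom was 4.83 for KO 1 with KO 2 and at least 21.4 for the other RNA-seq pairs, and at least 2.28 for CUT&Tag pairs. The tests were tried on simulated counts with 50 genes or regions changed per fold size. Over 15298 genes, edgeR recovered 14% of 1.5-fold, 64% of 2-fold, 90% of 4-fold and 96% of 8-fold changes, with 9 false among 141 calls; DESeq2 had 31 false among 175. Over 69209 regions, edgeR recovered 2%, 20%, 66% and 90%, with 2 false among 91 calls. Camera called 5 of 5 simulated lists shifted 1.4-fold and 0 of the others. The simulated genes were drawn independently and without the library split. False calls of lists whose genes vary together were therefore not tried. Figures were drawn with matplotlib 3.10.9. The authors' group means were not used. No genome sequence was used here, so GC content was not checked.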

Results

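The series measured neural stem and progenitor cells (NSPCs) from mouse brain, either wild type (WT) or labelled Mina53-KO. Mina53, whose current gene symbol is Riox2, is a JmjC-domain protein, and the series title assigns it arginine demethylase activity on histone H4 asymmetrically dimethylated at arginine 3. Poly(A) RNA sequencing covered 3 WT and 3 KO libraries, with 19923010 to 25939376 counts per library. CUT&Tag, in which a tethered transposase cuts DNA beside an antibody-bound chromatin feature, covered 2 WT and 2 KO libraries, with 2913959 to 4038765 reads in 69418 merged regions. The labels name no antibody, no spike-in, no brain region and no way in which the KO was made. They also do not say that the libraries came from separate animals or cultures, so the p-values measure only the spread between these libraries.

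The first comparison asked whether the targeted gene was lower in the libraries labelled KO. Riox2 (ENSMUSG00000022724) measured 18.5 ± 1.39 CPM in WT and 3.58 ± 0.279 CPM in KO (SD, n = 3 each), a log2 fold change of -2.37 (SE 0.15, adjusted p = 0.000324, edgeR). Each KO library lay below each WT library, and reads remained in each KO library. Among 8 tested genes listed beforehand as neighbours of Riox2 on chromosome 16 (camera adjusted p = 0.242), 1 was called: St3gal6, a sialyltransferase gene, fell from 48.2 ± 8.92 to 13.5 ± 1.29 CPM (log2 fold change -1.84, SE 0.16, adjusted p = 0.00108). The 18 tested genes of protein arginine methyltransferases and related demethylases included no called gene other than Riox2 (camera adjusted p = 0.289; 0.0299 by fry, with Riox2 in the list). Prmt5 measured 146 ± 2.64 CPM in WT and 130 ± 2.86 CPM in KO (adjusted p = 0.573).

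The second comparison asked which genes differed in expression between KO and WT NSPCs. The genes with the largest increases included transcription factors of brain patterning. Six3, a forebrain and eye factor, rose from 3.89 ± 0.719 to 38.1 ± 7.25 CPM (9.81-fold, adjusted p = 0.000327), and Emx2, a factor of the dorsal telencephalon, rose from 2.71 ± 0.507 to 14.6 ± 0.348 CPM. Hoxa7, a posterior Hox gene, rose from 0.756 ± 0.264 to 6.82 ± 1.11 CPM. The genes with the largest decreases also included patterning factors: Foxb1, expressed in the diencephalon and midbrain, fell from 7.37 ± 1.53 to 0.402 ± 0.0939 CPM (18.2-fold, adjusted p = 0.00034), and Lmx1b, a factor of midbrain and hindbrain neurons, fell from 5.58 ± 1.01 to 0.911 ± 0.365 CPM. Across the transcriptome, 525 of 15298 tested genes were called at an adjusted p under 0.05 by edgeR, 271 higher and 254 lower in KO. Of these, 157 higher and 141 lower genes changed by a log2 fold of at least 1.

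Thbs2, a thrombospondin, rose from 4.16 ± 0.871 to 33.8 ± 1.23 CPM, and Sulf1, an extracellular heparan sulfatase, rose from 6.62 ± 0.271 to 44.2 ± 1.14 CPM (adjusted p = 9.88e-05). Cbln1, a secreted synapse organiser, rose from 0.521 ± 0.44 to 5.97 ± 0.802 CPM, but its adjusted p was 0.0699 without WT 3. The synaptic genes Lrfn2 and Rimbp2 had log2 fold changes of 3.21 (SE 0.22) and 2.45 (SE 0.14). Rhox5, a homeobox gene of the X chromosome, had 2.43 (SE 0.25), and Epb41l4a had 1.85 (SE 0.11). Six3os1 had 3.06 (SE 0.14); it is an antisense partner of Six3, and the strand setting of the counting is not given in the sources used here, so the values of the pair are uncertain.

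The decreases included the basement membrane gene Nid1, which fell from 29.1 ± 2.02 to 6.65 ± 0.2 CPM (adjusted p = 0.000293). Car3, a carbonic anhydrase gene, fell from 56.6 ± 7.2 to 17.3 ± 0.319 CPM. Pdlim3 had a log2 fold change of -3.38 (SE 0.41), Odad2, a gene of ciliary dynein arms, of -3.32 (SE 0.27), the potassium channel gene Kcnn4 of -2.60 (SE 0.31), Syndig1l of -2.58 (SE 0.30) and the protease inhibitor gene Serpinb1a of -2.39 (SE 0.21). Pcdha7 had -2.41 (SE 0.24); it shares its constant exons with other genes of the protocadherin alpha cluster, so its count is uncertain. Muc2 had -2.80 (SE 0.45) and the lactate exporter gene Slc16a3 had -2.37 (SE 0.38). Both lost their call without WT 3, where their adjusted p was 0.0755 and 0.0672, and without KO 2, where it was 0.0636 and 0.0752. The other 22 of the 25 genes named by rule, Riox2 included, kept their call without each of the 6 libraries in turn.

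**Figure D1:**
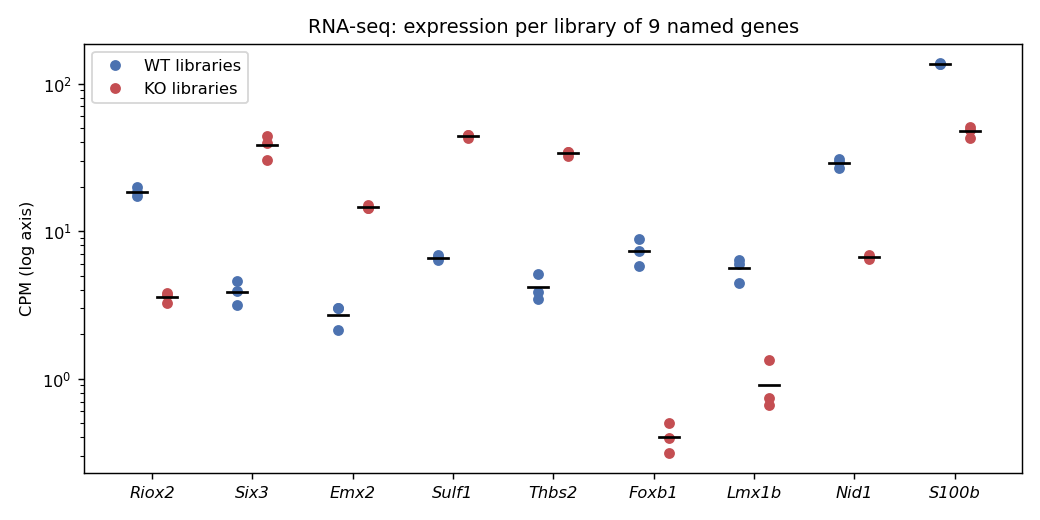
Expression of 9 named genes in each RNA-seq library, in CPM on a log axis; points are libraries (3 WT, 3 KO) and black lines group means. Riox2 averaged 18.5 CPM in WT and 3.58 CPM in KO. Apart from Riox2, the naming rule admitted only genes whose WT and KO libraries did not overlap.

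All 525 called genes had non-overlapping groups, which a call favours; of all tested genes 19.0% had them, against 10% by chance for 3 against 3. The count was 145 without WT 3, 179 without KO 1, 179 without KO 2 and 313 without WT 2, and DESeq2 called 958. The largest component of variation (47.4%) parted WT 1, KO 1 and KO 2 from WT 2, WT 3 and KO 3, whose mitochondrial shares of counts were 2.31% to 2.68% and 3.52% to 5.71%; with the parts as a covariate 1695 genes were called; the parts were read off the same counts, and this covariate lowered the common biological coefficient of variation from 17.9% to 9.06%.

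Markers of neuronal commitment were called higher in KO by the main test, but not with an estimated correlation. Of 11 tested markers of intermediate progenitors and neuroblasts, 4 rose and 7 did not pass, with a median log2 fold change of 0.90 (camera adjusted p = 1.4e-06, adjusted p = 0.0658 with an estimated correlation). Btg2, an antiproliferative gene of neurogenic divisions, rose from 69.3 ± 6.88 to 129 ± 0.72 CPM, and Cd24a, a neuroblast surface marker, from 56.9 ± 8.95 to 100.2 ± 12.5 CPM. Dlx1, a factor of forebrain interneuron progenitors, rose from 0.987 ± 0.443 to 3.38 ± 0.284 CPM. Of 17 tested neuron markers, 5 rose and 12 did not pass (median 0.28, camera adjusted p = 3.97e-05, adjusted p = 0.0658 with an estimated correlation). The neurofilament genes Nefm and Nefl rose 3.56-fold and 2.68-fold, and Gap43, a growth cone gene, rose 1.92-fold to 205 ± 31.2 CPM. Dlx1 and the called neuron marker Bcl11b are also forebrain patterning genes. Adjusted over the list alone, 8 progenitor markers were higher, and 7 neuron markers were higher and 1 lower.

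Astrocyte markers were called lower in KO by the main test, but not with an estimated correlation or by fry: 5 of 16 tested fell and 11 did not pass (median -0.26, camera adjusted p = 0.00291, adjusted p = 0.477 with an estimated correlation and 0.0971 by fry). S100b fell from 136 ± 0.843 to 47.3 ± 4.05 CPM, Sparcl1 from 318 ± 34.2 to 148 ± 13.8 CPM and Agt from 44.0 ± 9.33 to 15.1 ± 4.11 CPM. Slc1a3, a glutamate transporter gene also expressed in radial glia, fell 1.39-fold. The 20 neural stem and radial glia markers went both ways: Tnc rose from 421 ± 17.5 to 955 ± 19.2 CPM, Vim rose 1.62-fold, Hopx fell 2.06-fold and 17 did not pass (camera adjusted p = 0.359). Adjusted over the list alone, 5 astrocyte markers were lower, and 2 stem markers were higher and 2 lower.

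Markers of other cell types were tested as well. None of the erythroid markers was expressed enough to be tested. The 2 tested microglia markers, Lyz2 and Cd68, had adjusted p of 0.59 and 0.809. Among 4 endothelial and pericyte markers, Flt1 rose from 25.9 ± 4.02 to 56.4 ± 4.12 CPM and 3 did not pass. Among 8 fibroblast and meningeal markers, a list camera did not call (adjusted p = 0.989), Acta2 and Foxc1 fell 2.04-fold and 1.8-fold, and Twist1 rose from 0.107 ± 0.0579 to 0.72 ± 0.186 CPM. Of 14 oligodendrocyte lineage markers, Myrf rose 1.8-fold and 13 did not pass, and none of 4 ependymal markers passed. Adjusted over the list alone, the 4 endothelial and pericyte markers differed, 3 higher and 1 lower (median 1.00), 3 fibroblast and meningeal markers were higher and 2 lower, 1 oligodendrocyte lineage marker was higher and 1 lower, and no microglia or ependymal marker passed. Xist had 0 reads in each library, and the Y-linked genes Kdm5d and Ddx3y were expressed in all 6; Eif2s3y measured 73.2 ± 16.7 CPM in WT and 40.5 ± 6.59 CPM in KO (adjusted p = 0.0549).

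Cell cycle genes moved in part. Of 18 tested cyclin-dependent kinase inhibitors and G1 regulators, 4 rose and 14 did not pass (median 0.17, camera adjusted p = 0.00552, adjusted p = 0.165 with an estimated correlation). Those 4 act in opposed ways: Cdk6, Ccnd1 and Ccnd2 drive passage through G1, and Cdkn1a (p21) inhibits it. Cdk6 rose from 10.4 ± 1.34 to 51.1 ± 7.86 CPM, Ccnd1 and Ccnd2 rose 1.46-fold and 1.35-fold, and Cdkn1a rose from 360.0 ± 49.2 to 599 ± 98.0 CPM. Of 24 p53 target genes, Btg2, Cdkn1a and Pmaip1, a proapoptotic gene, rose and 21 did not pass (median 0.33, camera adjusted p = 2.19e-05, adjusted p = 0.0658 with an estimated correlation). Of 25 genes of G2 and M phase, Ccnb2 (cyclin B2) fell from 80.1 ± 4.44 to 51.6 ± 4.33 CPM and 24 did not pass (median -0.14, camera adjusted p = 0.00302, adjusted p = 0.225 with an estimated correlation and 0.0582 by fry). Adjusted over the list alone, 7 G1 genes were higher, 9 p53 targets were higher and 1 lower, and 1 G2 and M gene was lower.

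The lists of glycolysis and hypoxia and of cholesterol synthesis were called lower in KO by the main test, but neither was with an estimated correlation. Of 22 glycolysis and hypoxia genes, 5 fell and 17 did not pass (median -0.52, camera adjusted p = 3.8e-08, adjusted p = 0.477 with an estimated correlation and 0.151 by fry). Ndrg1 fell from 16.7 ± 4.29 to 4.48 ± 1.13 CPM, Bnip3 from 66.7 ± 8.96 to 31.6 ± 7.93 CPM, and Ldha, the muscle-type lactate dehydrogenase, from 919 ± 115 to 568 ± 63.3 CPM. Of 20 cholesterol synthesis genes, Lss, Fdft1, Stard4 and Dhcr7 fell, by 1.55-fold, 1.43-fold, 1.6-fold and 1.41-fold, and 16 did not pass (median -0.46, camera adjusted p = 1.46e-10, adjusted p = 0.0527 with an estimated correlation). Adjusted over the list alone, 12 glycolysis and hypoxia genes and 15 cholesterol genes were lower.

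The remaining lists with at least 5 tested members were not called, with camera adjusted p of 0.128 or more. Some held genes that changed. In the Wnt list, Sfrp1, a secreted Wnt antagonist, rose from 3.23 ± 0.409 to 16.5 ± 0.208 CPM and Fzd5 rose 1.76-fold, while Fzd9 fell from 191 ± 44.4 to 50.1 ± 12.2 CPM and Rnf43 fell 2.77-fold. In the hedgehog list, the co-receptor gene Cdon rose from 16.5 ± 0.849 to 53.6 ± 5.37 CPM; the median of that list was -0.12 and its mean 0.08. In the extracellular matrix list, Tnc, Lama1, Sparc and Lamb1 rose, Lama1 by 3.71-fold. Hey1 of the Notch list and Ltbp1 of the TGF-beta and BMP list rose 1.57-fold and 1.99-fold, Btg2 was the called member of the immediate early list, and in the interferon list Gbp3 rose 1.83-fold and Ifi35 fell 2.2-fold. No member was called in the lists of S phase and replication, DNA repair, apoptosis, FGF and EGF targets, ribosome biogenesis, ribosomal proteins, MHC class I, unfolded protein response, oxidative phosphorylation, histones, lysine methylation regulators or heat shock. Adjusted over the list alone, 5 extracellular matrix genes were higher and 6 lower, 4 Wnt genes were higher and 3 lower, and no other of these lists had more than 2 in a direction, except fibroblast and meningeal markers with 3 higher. For DNA repair, oxidative phosphorylation and lysine methylation regulators, median, mean and test differed in sign, with each median within 0.02 of 0.

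Of the 47 called list members that the naming rule picked, Riox2 apart, 12 kept their call without each of the 6 libraries in turn: Tnc, Btg2, Sparcl1, S100b, Cdk6, Sfrp1, Fzd9, Cdon, Lama1, Ltbp1, Flt1 and St3gal6. Insm1, a neuroblast marker, Ccnd2 and Ifi35 lost it in each of the 6 fits.

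**Figure D2:**
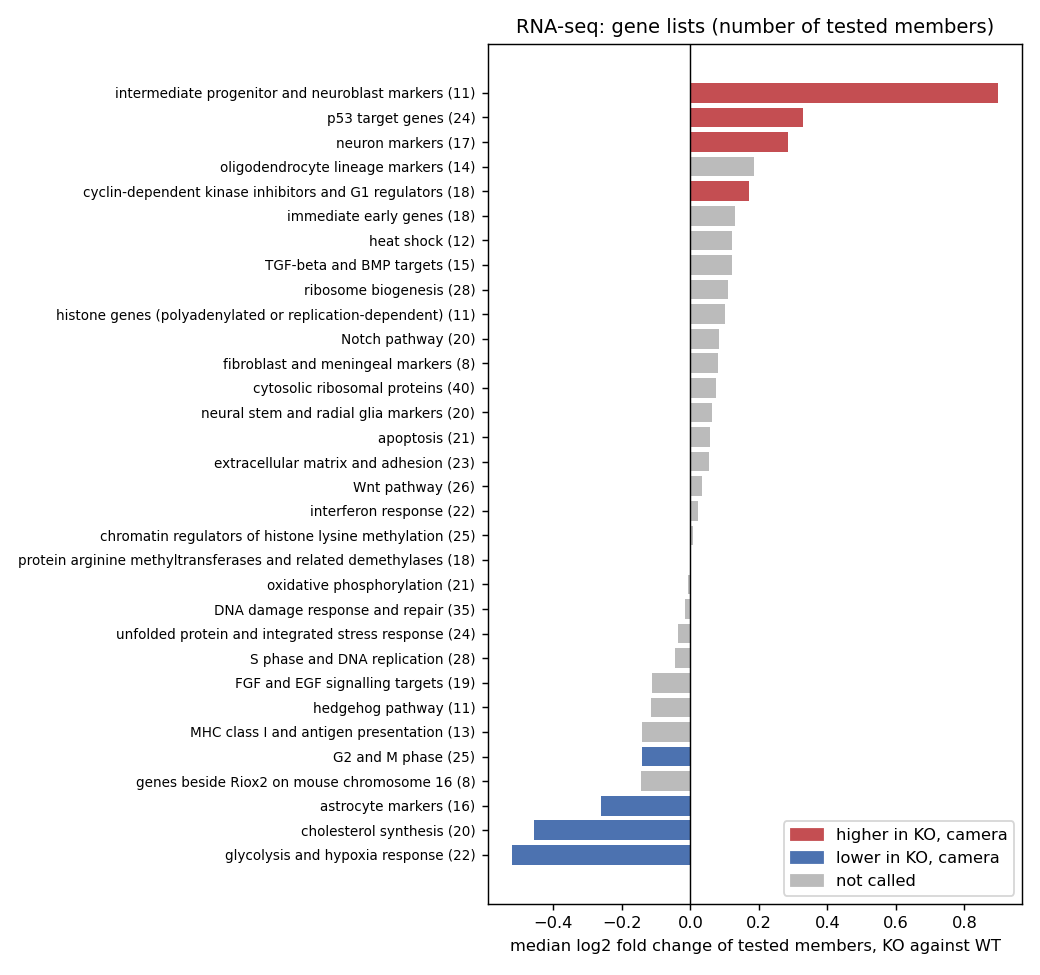
Median log2 fold change (KO against WT) of each gene list with at least 5 tested members; red and blue bars are lists called higher or lower by camera at an adjusted p under 0.05, and grey bars were not called. The medians run from -0.52 for glycolysis and hypoxia to 0.90 for intermediate progenitors and neuroblasts.

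The third comparison asked where the CUT&Tag signal differed between KO and WT. The gain with the smallest p lay at Nes, the gene of the neural stem cell filament nestin, downstream of its TSS by the deposited distance. The region at chromosome 3, 87881207 to 87882075 (GRCm39), which the authors annotated as promoter at 2771 bp from the Nes TSS, measured 36.1 ± 7.64 CPM in WT and 97.5 ± 10.9 CPM in KO (SD, n = 2 each, CPM of reads in regions; log2 fold change 1.43, SE 0.17, adjusted p = 4.58e-13, edgeR). A region at the promoter of Fnta, a farnesyltransferase subunit gene, at chromosome 8, 26493247 to 26493972, rose from 15.9 ± 0.898 to 40.9 ± 3.84 CPM (adjusted p = 4.49e-05). The 3 regions called lower all lay on chromosome 8, between 19.5 and 21.5 Mb. The intergenic region 19757117 to 19757965 fell from 132 ± 7.24 to 73.0 ± 3.22 CPM (log2 fold change -0.85), the region 20060834 to 20062709, annotated as promoter, from 216 ± 15.9 to 137 ± 0.0995 CPM, and the intergenic region 21486866 to 21487212, with the defensin gene Defa21 as the assigned gene, from 24.5 ± 4.74 to 9.39 ± 1.55 CPM (adjusted p = 0.0492).

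These were the 5 regions called among 69209 tested; 3704 (5.35%) had an unadjusted p under 0.05, and the median log2 fold change was 0.01. Only the Nes region was called without each of the 4 libraries in turn; the Fnta region had an adjusted p of 0.225 without KO 1, none of the 3 lower regions was called without KO 1 or without KO 2, and the count was 1 without KO 1, 2 without KO 2, 3 without WT 1 and 15 without WT 2. The Defa21 region lost its call with RLE size factors, library totals and DESeq2 (adjusted p 0.0544, 0.178 and 0.887), and the region 20060834 to 20062709 with library totals (0.0501), under which 4 regions were higher and 1 lower. In the authors' deposited table, all regions had a q-value of 1 and 1622 had a p under 0.05; its log2 fold change for the Nes region was 1.49. Further Nes regions measured 0.90 (SE 0.25) at the TSS and -0.11 (SE 0.24) at 11192 bp, neither called. Of the 100 uncalled regions in the chromosome 8 segment, 92 were lower in KO.

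**Figure D3:**
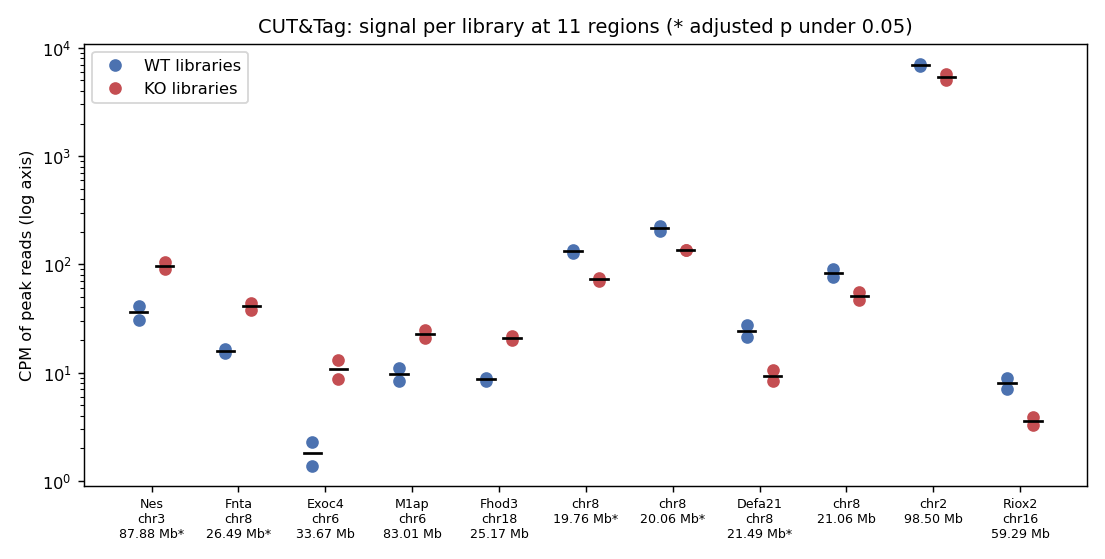
CUT&Tag signal in each library at 11 regions, in CPM of reads in regions on a log axis: the 5 with the smallest p in each direction and the Riox2 promoter region. Points are libraries (2 WT, 2 KO), black lines are group means, and stars mark the 5 called regions.

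Among the next regions by p, none passed. An intronic region of Exoc4 (chromosome 6, 33674011 to 33674358) had a log2 fold change of 2.54 (SE 0.63, adjusted p = 0.164), a promoter region of M1ap (chromosome 6, 83005503 to 83005966) 1.23 (SE 0.30, adjusted p = 0.164) and an intronic region of Fhod3 (chromosome 18, 25172148 to 25172639) 1.26 (SE 0.32, adjusted p = 0.227). The intergenic regions at chromosome 8, 21056501 to 21057322, and chromosome 2, 98496532 to 98497756, had -0.72 (SE 0.16) and -0.36 (SE 0.08), both with an adjusted p of 0.074. The chromosome 2 region held 19536 to 21913 reads per library, where the median count per region was 31 to 44, so it is not a typical region. The Riox2 promoter region (chromosome 16, 59292238 to 59292437) held 22 and 26 reads in WT and 16 and 11 in KO. Its log2 fold change of -1.15 (SE 0.63) was not called (adjusted p = 0.933, edgeR).

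**Figure D4:**
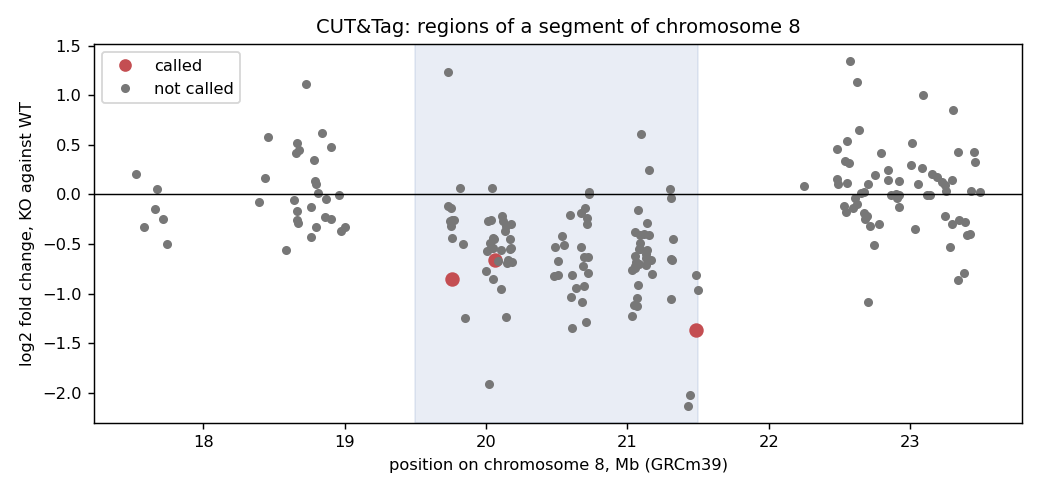
Log2 fold change (KO against WT) of each CUT&Tag region along chromosome 8, with position in Mb on GRCm39; red points are the 3 called regions, grey points are not called and the shading marks 19.5 to 21.5 Mb. Inside the shading 95 of 103 regions lie below 0, and the regions within 2 Mb of its ends have a median of 0.01.

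By annotation, promoter regions held 38.0% ± 0.356 of reads in regions in WT and 37.1% ± 0.156 in KO (SD, n = 2), and intronic regions 30.9% ± 0.036 and 31.6% ± 0.155. These shares depend on the regions called and were not tested. The authors marked peaks in each library, and 6965 regions (10.0%) were marked in all 4, while 4019 were marked in both KO and neither WT library and 834 in both WT and neither KO library. The KO libraries held more reads in regions and had 40699 and 30806 peaks against 20867 and 22821 in WT. The median log2 fold change was 0.29 for the 4019 regions, -0.54 for the 834 and -0.13 for those marked in all 4; the marks select for the sign of the first 2 medians. Of the 4019 regions, 2 were called.

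The last comparison asked whether CUT&Tag signal differed at genes whose RNA changed. Summed over the regions assigned to each gene, the 210 genes with higher RNA had a median log2 difference of 0.02 and the 200 with lower RNA of -0.04, against 0.01 for the other genes; neither set was called (camera adjusted p = 0.737 and 0.495). The sets stayed uncalled under each alternative tried. Of the 25 named genes, 22 had a region: Cbln1 and Emx2 each had a log2 difference of 0.75 (SE 0.50 and 0.47), Six3 0.13 (SE 0.25), Lmx1b -0.73 (SE 0.44) and Syndig1l -0.61 (SE 0.23, unadjusted p = 0.00787), and none passed the adjusted threshold. Foxb1 had no assigned region. In 11 of the 22 the sign was that of the RNA. By single regions, no gene called in RNA-seq was assigned a region called in the same direction. Only 2 genes with a higher region and 1 with a lower region entered, and 0.04 and 0.02 overlaps were expected. This comparison is thus too small to show whether the assays go together. By reads summed per gene, 40 of 27448 genes were called, 9 higher and 31 lower, but 6 with library totals, 12 with DESeq2, 13 without WT 1, 55 without WT 2, 7 without KO 1 and 11 without KO 2. Among the lower genes, at least Gm56829, Gm7807, Gm7760 and Defa21 were assigned regions of the chromosome 8 segment, so their calls are not independent. Others of the lower genes may lie in that segment too, and their positions are not reported here. The higher genes included the mitochondrial tRNA genes mt-Tl1 and mt-Th (log2 difference 0.25 and 0.22). Mitochondrial reads were 3.60% and 3.67% of reads in regions in KO 1 and KO 2. In WT 1 and WT 2 they were 3.12% and 3.05%. Nes, also among the 40, had a log2 difference of 0.99 (SE 0.12, adjusted p = 5.56e-13, edgeR). It was not called in RNA-seq (adjusted p = 0.183, edgeR). Of the 40, 3 were also called in RNA-seq, in the same direction: Tshz2 was higher (log2 difference 0.49 in CUT&Tag, adjusted p = 0.0214, and 2.18 in RNA), and Tmem267 (-0.35, adjusted p = 0.0214, and -0.75) and Erdr1y (-0.34, adjusted p = 0.0328, and -0.85) were lower. The overlap was 1 against 0.07 expected for higher and 2 against 0.19 expected for lower genes (two-sided Fisher's exact test, adjusted p over the 4 pairs of directions = 0.144 and 0.0611). All 3 lost their CUT&Tag call with library totals, with DESeq2, without KO 1 and without KO 2, and so did Tmem267 and Erdr1y without WT 1 and Tshz2 without WT 2. At an unadjusted p under 0.05 for single regions, 18 genes were higher in both against 9.02 expected (two-sided Fisher's exact test, p = 0.00506, adjusted p over the 4 pairs of directions = 0.0203) and 25 lower in both against 25.7 expected (p = 1); the number of regions per gene was not taken into account.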

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

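The library split, the left-out mitochondrial genes, the TSS windows and the overlap by reads summed per gene were chosen after the results were seen; the other settings were planned. No result changed direction where either fit called it, and the causes of the changes below were not tested except where the setting itself leaves out a library. Of the RNA-seq calls, DESeq2 made 958 (482 higher, 476 lower; 523 of the 525 shared), glmTreat 318 (161 and 157), and the split as a covariate, read off the same counts, 1695 (902 and 793). The labels do not say whether replicate numbers mark pairs. Deviations of same-numbered libraries from their group means correlated at 0.46, -0.37 and 0.27 across genes in RNA-seq and at 0.02 in CUT&Tag. The RNA-seq deviations also carry the library split, so these values cannot settle whether the libraries were paired. With the replicate block, 229 genes (112 higher, 117 lower; 186 with a log2 fold of at least 1) and 9 regions (7 lower) were called. With 1 RNA-seq library left out, calls ranged from 145 (without WT 3) to 506 (without KO 3), higher genes from 78 to 259, lower genes from 67 to 247, genes with a log2 fold of at least 1 from 129 to 306, the Riox2 log2 fold change from -2.43 to -2.31 and lists called from 8 to 11; 4 calls of uncalled lists were gained and none of the 8 called lists was lost. Without KO 3, the remaining KO libraries all lie in the part of the library split that holds WT 1. Without WT 1, the remaining WT libraries all lie in the other part. Genotype then goes partly with the split, and 421 and 409 of the genes called in those fits were shared with the main fit. With an estimated correlation 0 lists were called, and fry lost 3 and gained 1. RLE, totals and both prior counts changed no list call. Library totals called 4 CUT&Tag regions higher and 1 lower, and DESeq2 4 higher. Without 1 CUT&Tag library, 1 to 15 regions were called, 1 to 2 higher and 0 to 13 lower. Signal at genes called higher or lower in RNA-seq stayed uncalled, with mean differences from other genes of -0.01 to 0.02 and -0.05 to -0.02 without 1 library. At an unadjusted p under 0.05 in CUT&Tag, 43 genes overlapped in direction in place of 0 by called regions, and 3 did by reads summed per gene. Called gene sums fell from 40 to 6 with library totals and 12 with DESeq2, and ranged from 7 to 55 without 1 library. In simulated counts 2-fold changes were recovered for 20% of regions and 64% of genes; the assays differ in depth, replicates and number of features, whose effects were not separated.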

Other observations

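Tests of gene length and of mitochondrial reads were set down before their results were seen; the brain-region lists, the GO terms, the counts over other splits and the tests on chromosome 8 and Nes were chosen after the results were seen.

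Genes that pattern the brain along its axis moved apart between the genotypes. Of 11 tested telencephalic and anterior forebrain genes, 7 were higher in KO, among them Six3, Emx2, Bcl11b, Dlx1 and Lhx2, which rose from 7.74 ± 0.991 to 39.3 ± 4.80 CPM (SD, n = 3; list median 1.77, camera adjusted p = 6.03e-16, adjusted p = 0.0122 with an estimated correlation). Of 16 tested genes of the diencephalon, midbrain and rostral hindbrain, 7 were lower: besides Foxb1 and Lmx1b, En2 fell from 8.93 ± 2.29 to 2.68 ± 0.202 CPM, Otx1 from 18.1 ± 3.28 to 6.47 ± 1.22 CPM, Barhl2 from 9.56 ± 3.01 to 1.92 ± 0.605 CPM, Gata3 from 1.54 ± 0.307 to 0.471 ± 0.194 CPM and Pax3 from 2.19 ± 0.547 to 0.013 ± 0.0225 CPM (list median -0.80, adjusted p = 2.53e-16, adjusted p = 0.0283 with an estimated correlation). Of 6 tested Hox genes, Hoxa7 and Hoxa5 were higher and 4 did not pass (camera adjusted p = 0.0507). Adjusted over the list alone, 2 Hox genes were higher and 1 lower. These lists were written after such genes had been seen among the calls, so their p-values are not independent evidence. Their p-values were adjusted over the brain-region lists alone, and those of the planned lists over 32 lists. The adjusted p of the brain-region lists, also with an estimated correlation, can therefore not be set against those of the planned lists. Which gene went into which list was also a choice, on which the medians depend. Pax6, a forebrain gene tested with the stem and radial glia markers, was not in the telencephalic list. Its log2 fold change was -0.49 (adjusted p = 0.0571, edgeR).

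Cell adhesion terms had the smallest p in both directions, in a one-sided Fisher's exact test over 1710 terms and 12370 genes. At an adjusted p under 0.05, 5 terms passed in each direction. Homophilic cell adhesion held 15 genes higher in KO (2.45 expected, adjusted p = 3.62e-05) and 13 lower (2.36 expected, adjusted p = 0.000838). Most were clustered protocadherins: 2 of 11 tested Pcdha genes were higher and 2 lower, 2 and 3 of 21 Pcdhb genes, and 6 and 6 of 22 Pcdhg genes. Pcdha and Pcdhg genes share constant exons, so the split of their reads is uncertain. Anterior/posterior pattern specification held 7 higher genes (adjusted p = 0.0263), and negative regulation of neuron apoptotic process held 9 lower genes (adjusted p = 0.0321).

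The first pattern is the split of WT 1, KO 1 and KO 2 from WT 2, WT 3 and KO 3, which called 3280 genes, against 525 for the genotypes. The parts were read off the largest component of variation of the same counts, so many calls between them are expected. As large a count as the real one came from 2 of 10 splits for genes (525, highest other 3280) and from 2 of 10 for lists (8, highest other 9). For genes, the 3280 came from the split above, read off the same counts, and each remaining split called 0. With 10 splits the share cannot go under 0.05. Gene length bias was argued against as the whole cause: 3163 calls were left after a length trend was removed per library (rho across genes 0.17 before, 0.05 after). For mitochondrial reads taking part of the library, 3253 calls were left without mitochondrial genes, but TMM scaling takes up such a share in either fit and the count hardly moved, so that the bound set beforehand decides nothing and this explanation stays open. No biological explanation of the split was tested, since the labels give none.

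The second pattern is that of the brain-region genes. The smaller camera p of the 2 lists was as low as the real one in 1 of 10 splits, the real one itself (8.44e-17, next lowest 1.79e-06). With 10 splits the share cannot go under 0.05, and the lists were written from calls of the real split, which favours it. Camera also called both lists in most of the other splits. Each of those splits sets 2 libraries of a genotype against 1, so part of a genotype difference remains in it. Calls in them therefore cannot decide whether a camera call marks the genotypes. That KO and WT cells were taken from different brain regions may account for a difference of 2.57 between the list medians, and an effect of the genotype on regional identity may do so as well. The 2 cannot be told apart, because region of origin is not in the labels and would go with genotype. The 6 tested Hox genes, with 2 higher and 0 lower, do not follow a plain shift towards the front. Adjusted over the list alone, however, 1 of them was lower.

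The third pattern is that of the CUT&Tag calls on chromosome 8 and at Nes. A loss confined to the 3 called regions was argued against: the 100 uncalled regions from 19.5 to 21.5 Mb had a median of -0.55 (quartiles -0.77 and -0.30), and the 99 regions within 2 Mb of the segment a median of 0.01. Fewer copies of a repeated segment, or reads placed elsewhere, is a candidate explanation. Of the uncalled regions 92% were lower, and 3 of the lowest 4 of 3000 windows of 500 kb lay there. But no input DNA was analysed here, and a loss of the CUT&Tag target, which the labels do not name, across the segment stays open. For Nes, extra copies of a wide segment were argued against by a median of -0.13 over 28 regions of other genes within 200 kb. Extra copies of a short Nes fragment, as in a construct with Nes regulatory sequence, and a gain of the CUT&Tag target cannot be told apart. The region at the TSS had 0.90 (SE 0.25, adjusted p = 0.348, edgeR), and the labels do not say how the KO was made.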
